A study of Mus musculus with 4 samples.

How the data were processed

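The RNA of 4 mouse T cell libraries was measured by RNA sequencing. The labels name 2 groups of 2 libraries each: wild-type (WT) cDNT cells and cDNT cells labelled Tbx21-KO. The series title speaks of double-negative T cells, and the labels do not spell out what the "c" in cDNT stands for. The design text calls the second group a knockdown, whereas the sample labels call it a knockout. The label Tbx21-KO is used here. RNA was extracted with a column kit and made into libraries with an mRNA sequencing kit, per the labels' protocols. The aligner, the counting tool and whether counting used strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

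The deposited table gives FPKM values (fragments per kilobase of gene, scaled to library size) that the authors computed for each gene and library. The genome builds GRCm38 and mm10 are named in the submitters' processing notes. The table held 24769 rows. The last row breaks off inside a value and was left out, which left 24768 genes. Ensembl gene IDs were matched to symbols and coordinates of the mouse GENCODE annotation release M21 (GRCm38), and 24720 IDs matched. The other 48 kept their ID. The table has rows for 15385 of the 21951 protein-coding genes of that annotation. Of the 433 gene symbols in the lists described below, 38 matched no row. Some of these are other symbols of genes that have a row and are analysed, such as Cd244 for Cd244a and Atp5f1a for Atp5a1. The rest, among them Cd8a, are not analysed here. In all, 708 genes were at 0 in every library.

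FPKM values are not counts, but the library totals behind them could be estimated. With the summed exon length of each gene in the annotation, the low values of a library were whole multiples of what 1 read is worth. Of the values under 20 reads, 96.8% to 97.3% per library came out whole within 0.1 read. The library totals this implies were 24967028 and 24129889 reads for WT cDNT 1 and 2 and 23342603 and 24032883 for Tbx21-KO cDNT 1 and 2. At these depths 1 read in a gene with 2 kb of exon corresponds to 0.02 to 0.0214 FPKM. The genes of the table hold 99.0% to 99.1% of these totals, although many annotated genes have no row and the annotation used by the authors is not given in the sources used here. The totals therefore need not be the full sequencing depth.

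Replicates were compared before they were averaged. The 2 libraries of each group differed by more than counting noise: the median chi-square per gene was 1.27 for the WT pair and 1.17 for the Tbx21-KO pair, against 0.45 from counting alone. Each was kept as a replicate, though separate preparations of the same cells could also differ by more than counting noise. No label says that they came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

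Values were tested as log2(FPKM + 1), with a pseudocount of 1, in genes with a mean FPKM of at least 1 over the 4 libraries (11013 genes). The comparison of Tbx21-KO with WT was fitted with limma 3.58.1 in R 4.3.3, with variances moderated along an intensity trend. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called higher or lower. All log2 fold changes are Tbx21-KO minus WT on the log2(FPKM + 1) scale, which understates the change of low genes. An exact permutation test of a single gene cannot go below a two-sided p of 0.33 with 2 libraries against 2, so no such test was used. The steps were tested on simulated data with the means of the 2 WT libraries and a dispersion of 0.00194 estimated from that pair. Changes were placed only in genes with many reads in WT, 49 or 50 tested per fold. Recovery among low genes, or with as many changed genes as were called in the data, was therefore not tested. Of these changed genes the fit recovered 14.3% of the 1.25-fold changes, 71.4% of the 1.5-fold changes, 95.9% of the 2-fold changes and 100% of the 4-fold changes. Among all 10404 simulated genes tested, it called 17 unchanged genes, beside 7, 35, 47 and 50 changes recovered at these folds. That is a larger share of false calls than an adjusted p of 0.05 aims at. With no change simulated it called 6 genes. Every simulated gene had the same dispersion, which real genes need not have.

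The test, the alternatives, the rule for naming genes and 27 gene lists were fixed before the data were examined. The lists cover T cell programmes and general cell functions, and markers of other cell types. Lists with at least 3 measured genes (25 lists) were tested with limma's camera, which compares a list with the remaining genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera was repeated with the correlation estimated from the data. Named genes were chosen as follows. Tbx21 comes first. Next are the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05 whose groups do not overlap, leaving out IDs with no symbol, symbols made of Gm plus digits, and symbols ending in Rik or -ps. From each list, up to 4 called members with the smallest p are taken, or the 1 member with the smallest p where none passed. All measured members of the type 1 and cytotoxic lists can be named, and Tbx21, Eomes, Ifng, Gzmb, Prf1, Fasl, Lag3, Cd4, Cd8a and Cd3e are given where measured. Genes outside this rule were chosen after their values were seen, and the text says so. Families of symbols were also looked at after the values were seen: Klra, Trbv, Trav, aminoacyl-tRNA synthetase, Stfa, Trdv, Trgv, Serpinb, Slc7a, Ear, Ccl, ribosomal and mitochondrial genes, of which the text describes the first 3.

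The alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, rescaling to TPM, median-of-ratios scaling, quantile normalization, no variance trend, a robust fit, a replicate block, leaving out each library, an adjusted p of 0.1, a log2 fold change of at least 1, and an estimated inter-gene correlation. Chosen after seeing the data were 3 more: rescaling the libraries to the T cell receptor list, limma's voom on the recovered reads, and only genes with a mean WT FPKM of at least 1.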

Results

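The RNA of cDNT cells, a kind of double-negative T cell, was compared between WT cells and cells labelled Tbx21-KO. Tbx21 encodes T-bet, the transcription factor of the type 1 programme of lymphocytes. The series title places the comparison under the question of what T-bet does for the regulatory function of double-negative T cells, which are T cells without the CD4 and CD8 coreceptors. Each group had 2 libraries, and the FPKM values imply totals of 23342603 to 24967028 counted reads, which need not be the full sequencing depth. In this comparison 13 of 14 natural killer (NK) receptor genes were lower in Tbx21-KO and 1 was higher. Of 17 cytotoxic genes 10 were lower and 4 higher, and of 18 type 1 effector genes 11 were lower and 6 higher. With the libraries rescaled to the T cell receptor list, 9 type 1 genes were lower and 8 higher, against 508 lower and 7906 higher among all 11013 genes tested. Higher in Tbx21-KO were 11 of 12 type 17 genes and 11 of 15 type 2 genes, with 1 and 2 lower. Many genes of granulocytes and other myeloid cells were far higher in both Tbx21-KO libraries than in both WT libraries. The tests of whole lists rest on a preset inter-gene correlation, and no list was called with an estimated correlation.

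Tbx21 itself (ENSMUSG00000001444, protein-coding, GRCm38 chromosome 11, 97098071 to 97115331) was at 13.2 and 11.7 FPKM in WT 1 and 2 and at 2.29 and 2.41 FPKM in Tbx21-KO 1 and 2. It fell to 18.8% of the WT mean, a log2 fold change of -2.01 (SE 0.08, limma adjusted p = 8.21e-05). The values correspond to 823 and 703 reads in WT and 133 and 144 reads in Tbx21-KO. They sum over the whole gene, so they do not show in which exons the remaining reads lie. With a pseudocount of 5 the log2 fold change was -1.25.

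Across the 11013 genes tested, 3315 were higher and 2531 lower in Tbx21-KO (limma, adjusted p under 0.05), which is 53.1% of the genes. Of these, 869 rose and 205 fell by at least 1 on the log2 scale. Of the 3315 higher genes, 630 had a WT mean under 1 FPKM. The split depended on scaling: 56.7% of the calls were higher with the deposited values, 39.1% after quantile normalization and 94.0% with the libraries rescaled to the T cell receptor list, a scaling chosen after seeing the data. These scalings moved the median of all genes by -0.14 and 0.40 on the log2 scale. Changes close to that size have no settled direction.

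The 10 largest rises were all genes of granulocytes and their precursors or of related myeloid cells: Ngp, S100a9, Elane, Chil3, S100a8, Prtn3, Camp, Prg2, Ctsg and Mpo. S100a9 (GRCm38 chromosome 3, 90692632 to 90695721), a calcium-binding protein that is abundant in neutrophils, was at 2.34 ± 0.05 FPKM in WT (SD, n = 2) and 3962 ± 149 FPKM in Tbx21-KO (SD, n = 2), a log2 fold change of 10.21 (SE 0.04, adjusted p = 7.78e-07). Elane, the neutrophil elastase gene, went from 0.314 ± 0.33 to 1072 ± 21.6 FPKM. Ngp, a neutrophil granule protein, went from 1.27 ± 0.50 to 3200 ± 15.9 FPKM (SD, n = 2 each). All 11 measured granulocyte and mast cell markers rose, also when adjusted over the list alone, with a median log2 fold change of 4.76 (camera adjusted p = 2.63e-08, and adjusted p = 0.32 with an estimated correlation). They include Csf3r, the receptor of the granulocyte growth factor, at 0.00574 FPKM in WT and 15.8 FPKM in Tbx21-KO, and Cpa3, a mast cell and basophil protease, at 2.27 and 36.5 FPKM. In WT, 6 of the 11 were at 1 FPKM or more, so the others passed the filter through the Tbx21-KO libraries, which favours rises.

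Other cell type markers moved with them. All 8 measured macrophage and monocyte markers rose, also when adjusted over the list alone (median log2 fold change 2.09, camera adjusted p = 0.000113, adjusted p = 0.37 with an estimated correlation). In WT, 4 of the 8 were at 1 FPKM or more, so the others passed the filter through the Tbx21-KO libraries, which favours rises. Lyz2, which encodes lysozyme, rose from 3.26 ± 0.82 to 207.0 ± 13 FPKM (SD, n = 2 each), and Cd14 and Itgam rose by 3.31 and 2.99 on the log2 scale. Of 11 dendritic cell markers, 8 rose and none fell (8 higher and 1 lower adjusted over the list alone), among them Batf3 and the antigen presentation genes H2-Aa, H2-Eb1 and Cd74. This list had a median of 1.03 and a camera adjusted p of 0.00525, or an adjusted p = 0.46 with an estimated correlation, and its camera call was lost with the T cell list scaling. The dendritic markers Itgax, Xcr1 and Ccl17, named after their values were seen, were not called, with log2 fold changes of -0.22, -0.29 and 0.19. All 3 measured B cell markers rose, also when adjusted over the list alone, but they were Blk and Igkc, with log2 fold changes of 2.90 and 2.32, and Ighm, with 0.16, whose call was lost in 6 other fits (camera adjusted p = 0.038, adjusted p = 0.37 with an estimated correlation). Blk is also expressed by a subset of gamma delta T cells. The B cell list lost its call without a variance trend and with the T cell list scaling.

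**Figure D1:**
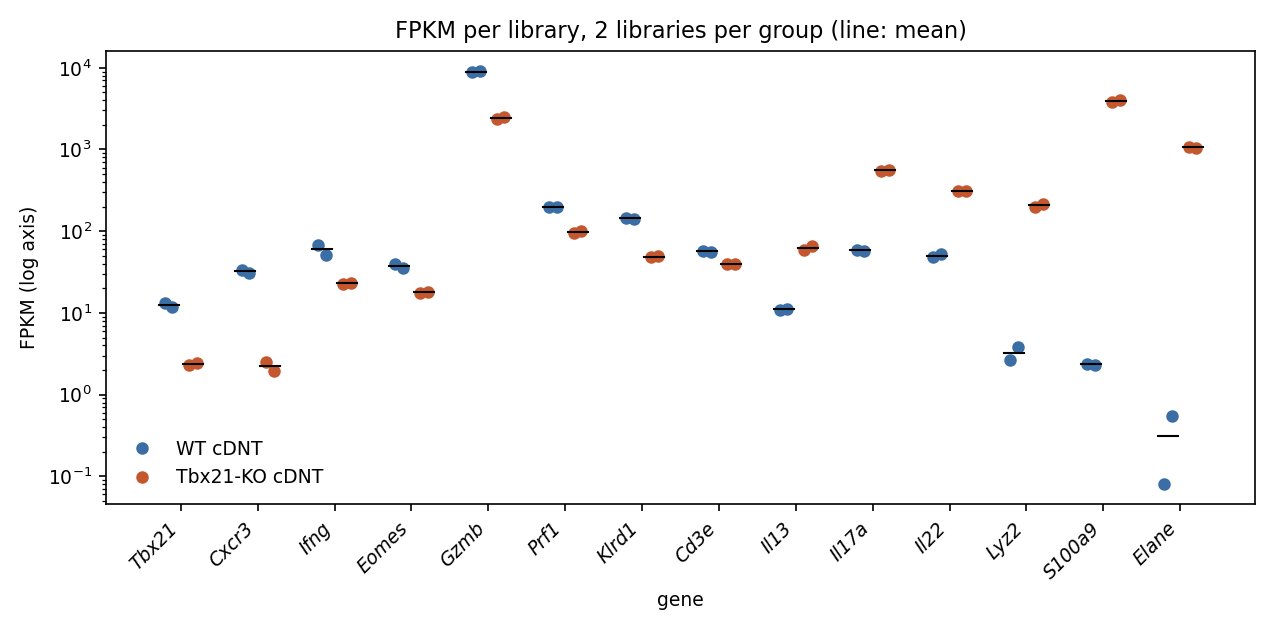
FPKM on a log axis of 14 genes in each of the 4 libraries, with 2 WT (blue) and 2 Tbx21-KO (orange) points per gene and a black line at each group's mean. Tbx21, Cxcr3, Ifng, Eomes, Gzmb, Prf1, Klrd1 and Cd3e lie lower in both Tbx21-KO libraries than in both WT libraries, and Il13, Il17a, Il22, Lyz2, S100a9 and Elane lie higher.

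The type 1 effector list, which holds genes that T-bet-expressing lymphocytes use, had 18 measured members. Of these, 11 fell, 6 rose and 1 was not called, with the same counts adjusted over the list alone. Cxcr3 (GRCm38 chromosome X, 101731535 to 101734269), the chemokine receptor of type 1 T cells, fell to 6.87% of its WT mean, from 32.5 ± 1.99 to 2.24 ± 0.41 FPKM (SD, n = 2 each). Xcl1, a chemokine that attracts dendritic cells, fell to 8.55%, and Il12rb2, a chain of the interleukin-12 receptor, to 29.0%. Ifng, which encodes interferon gamma, was at 59.8 ± 11.9 FPKM in WT and 23.0 ± 0.75 in Tbx21-KO (SD, n = 2 each), a log2 fold change of -1.33 (SE 0.14, adjusted p = 0.00151). Eomes, the T-box factor related to T-bet, fell by 1.05 on the log2 scale, Ccl4 by 1.26, Il18r1 by 1.14, Il2rb by 0.85 and Il18rap by 0.66. Ccl3, Hlx, Prdm1, Tnf, Ccl5 and Runx3 rose instead, with log2 fold changes of 1.48, 1.21, 0.69, 0.64, 0.58 and 0.20. Stat4 and Havcr2 were lower by 0.22 and 0.28 on the log2 scale, a size that the T cell list scaling turned around, and Bhlhe40 was not called. The call of Stat4 was also lost in 7 other fits, and that of Havcr2 in 1 other fit besides that scaling. Those of Ccl5 and Runx3 were lost in 1 fit each. The list's median was -0.47 (camera adjusted p = 0.038, adjusted p = 0.37 with an estimated correlation), and with the T cell list scaling 8 genes were higher and 9 lower, with a median of -0.03. Its camera call was lost with median-of-ratios scaling, quantile normalization, a mean FPKM of at least 5 and a mean WT FPKM of at least 1. With the T cell list scaling, where 508 of all 11013 genes were lower, that call was kept.

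Of 17 measured cytotoxic effector genes, 10 fell, 4 rose and 3 were not called (11 lower and 4 higher adjusted over the list alone). Gzmb (GRCm38 chromosome 14, 56258838 to 56262260), which encodes the protease granzyme B, was among the most abundant transcripts of the WT cells, at 8987 ± 67.3 FPKM, and fell to 2428 ± 70.2 FPKM in Tbx21-KO (SD, n = 2 each). The log2 fold change was -1.89 (SE 0.06, adjusted p = 4.34e-05), and its share of the summed FPKM was 2.9% in each WT library and 0.76% in each Tbx21-KO library. Prf1, which encodes the pore-forming protein perforin, fell by 0.98 on the log2 scale, Fasl by 1.01, Nkg7 by 1.34, Ctsw by 1.69 and Serpinb9, an inhibitor of granzyme B, by 1.32. Gzmc, Gzmk, Gzmm and Tnfsf10 fell as well, by 0.96, 1.04, 0.71 and 0.78. Srgn, Cst7, Gzmf and Lamp1 rose by 0.69, 0.67, 0.32 and 0.29. The calls of Gzmm, Lamp1 and Gzmf were lost in 4, 2 and 1 other fits. Gzmd, Gzme and Gzmg were not called, with log2 fold changes of -0.28, -0.26 and -0.01. Granzymes C to G are near-identical copies whose reads can be split between them, so their single values are uncertain. The list's median was -0.78 (camera adjusted p = 0.00505, adjusted p = 0.45 with an estimated correlation), or -0.43 with 6 higher and 9 lower with the T cell list scaling. Its camera call was kept with that scaling, and was lost after quantile normalization and at a mean FPKM of at least 5.

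NK receptors fell further than any other list by median. Of 14 measured genes, 13 fell and 1 rose, also when adjusted over the list alone, with a median log2 fold change of -1.35 (camera adjusted p = 7.35e-07, adjusted p = 0.37 with an estimated correlation). Klra7 (GRCm38 chromosome 6, 130218605 to 130233322), an inhibitory receptor of the Ly49 family, fell from 130.8 ± 2.27 to 19.4 ± 0.47 FPKM (SD, n = 2 each). Klrd1, the CD94 chain, fell by 1.54 on the log2 scale, Klre1 by 1.66, and Cd244a fell by 1.62. The Ly49 genes share near-identical sequence, so single Klra values are uncertain, but all 7 measured Klra genes, a family chosen after its values were seen, fell under each scaling, with a median of -2.41. The exception in the list was Tyrobp, named after its value was seen, an adaptor that myeloid cells also express, which rose by 1.31 on the log2 scale. Klra7, Klra5, Klra6 and Klra1 were among the 10 largest falls, beside Cxcr3, Xcl1, Ctse, Ppp2r2c, Itga1 and Zfp683. Zfp683, which encodes the factor Hobit of tissue-resident lymphocytes, and Itga1, an integrin chain of such cells, fell to 9.92% and 12.8% of WT.

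The T cell receptor complex list also fell, in the same 2 libraries that held the granulocyte transcripts. Of 19 measured genes, 14 fell, 1 rose and 4 were not called, with the same counts of rises and falls adjusted over the list alone, and the median was -0.49 (camera adjusted p = 3.69e-05, adjusted p = 0.32 with an estimated correlation). Cd3e, a chain of the CD3 complex, fell from 56.6 ± 0.76 to 40.0 ± 0.29 FPKM (SD, n = 2 each), a log2 fold change of -0.49. Cd28, Lck, Trac and Ptprc fell by 1.41, 1.24, 0.88 and 0.83. Cd5 rose by 0.53, and Cd3g, Zap70, Lat and Cd6 were not called, with log2 fold changes of -0.14, -0.09, 0.08 and 0.15; these 5 were named after their values were seen. The call of Cd5 was lost in 2 other fits, and that of Cd3e with the T cell list scaling. With the libraries rescaled to this list, 7 of its genes were higher and 7 lower. Of the CD4 and CD8 lineage markers, Cd4 was at 1.79 ± 0.07 FPKM in WT and 2.02 ± 0.01 FPKM in Tbx21-KO (SD, n = 2 each) and was not called (adjusted p = 0.292). Zbtb7b and Cd40lg of that list rose by 1.21 and 2.20, and Cd8b1, named after its value was seen, was not called (4 measured genes, 2 higher, also over the list alone, camera adjusted p = 0.112, adjusted p = 0.50 with an estimated correlation). All 4, including Cd4 and Cd8b1, were called higher with the T cell list scaling.

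Type 17 genes rose. Of 12 measured members, 11 rose and 1 fell, also when adjusted over the list alone, with a median log2 fold change of 2.10 (camera adjusted p = 7.07e-06, adjusted p = 0.32 with an estimated correlation). Il17a (GRCm38 chromosome 1, 20730905 to 20734496), which encodes interleukin-17A, rose 9.54-fold, from 58.3 ± 0.96 to 556.2 ± 9.70 FPKM (SD, n = 2 each). Il22 rose 6.21-fold to 310.4 FPKM and Il17f 4.65-fold to 42.9 FPKM. The gene that fell was Ahr, named after its value was seen, by 0.41 on the log2 scale. With the T cell list scaling 11 of the 12 were still higher and Ahr was not called. These genes rose in the libraries in which S100a9 was at 3856 and 4068 FPKM.

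Of 15 measured type 2 genes, 11 rose, 2 fell and 2 were not called (12 higher and 2 lower adjusted over the list alone), with a median of 1.27 (camera adjusted p = 0.00505, adjusted p = 0.37 with an estimated correlation). Il13 rose 5.54-fold to 61.8 FPKM and the chemokine receptor gene Ccr4 7.30-fold to 25.6 FPKM. Il9 was at 0.53 ± 0.20 FPKM in WT and 13.1 ± 0.62 FPKM in Tbx21-KO (SD, n = 2 each). Gata3, the transcription factor of the type 2 programme, and Nfil3 were not called, with log2 fold changes of -0.13 and 0.13, while Il4ra and Il10 fell by 0.15 and 0.68; these 4 were named after their values were seen. The calls of Il4ra and Il10 were lost in 4 and 2 other fits. With the T cell list scaling 14 of the 15 genes were higher and none lower, Il4ra and Gata3 turning to 0.30 and 0.28, and after quantile normalization 9 were higher and 3 lower. In WT, 10 of the 15 genes were at 1 FPKM or more, and the list's camera call was lost among genes with a mean WT FPKM of at least 1 and at a mean FPKM of at least 5. Mast cells and basophils, whose markers rose in the same libraries, express some type 2 cytokine genes too.

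Inhibitory and regulatory molecules, the list closest to the question in the series title, moved both ways: of 17 measured genes 10 rose, 5 fell and 2 were not called, with the same counts of rises and falls adjusted over the list alone. The list as a whole was not called (median 0.34, camera adjusted p = 0.433, adjusted p = 0.57 with an estimated correlation). Lag3, an inhibitory receptor for MHC class II, fell from 66.9 ± 0.53 to 29.2 ± 0.71 FPKM (SD, n = 2 each), a log2 fold change of -1.17 (SE 0.04, adjusted p = 5.61e-05). Entpd1, which encodes the ectonucleotidase CD39, fell by 1.46. Nt5e, which encodes CD73, Fgl2 and Il10, named after their values were seen, fell by 1.08, 1.07 and 0.68, the fall of Il10 losing its call with no filter and with the T cell list scaling. The largest rise was that of Ebi3, a subunit of interleukin-27 and interleukin-35, also named after its value was seen, from 2.65 ± 0.51 to 17.3 ± 2.47 FPKM (SD, n = 2 each), a log2 fold change of 2.33. Icos, Pdcd1, which encodes the checkpoint receptor PD-1, and Il2ra rose by 1.29, 1.53 and 0.87. These rises were seen in the libraries in which the myeloid markers S100a9 and Lyz2 averaged 3962 and 207.0 FPKM. Which cells they came from was not tested. In this list 11 genes were higher and 4 lower with the T cell list scaling.

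**Figure D2:**
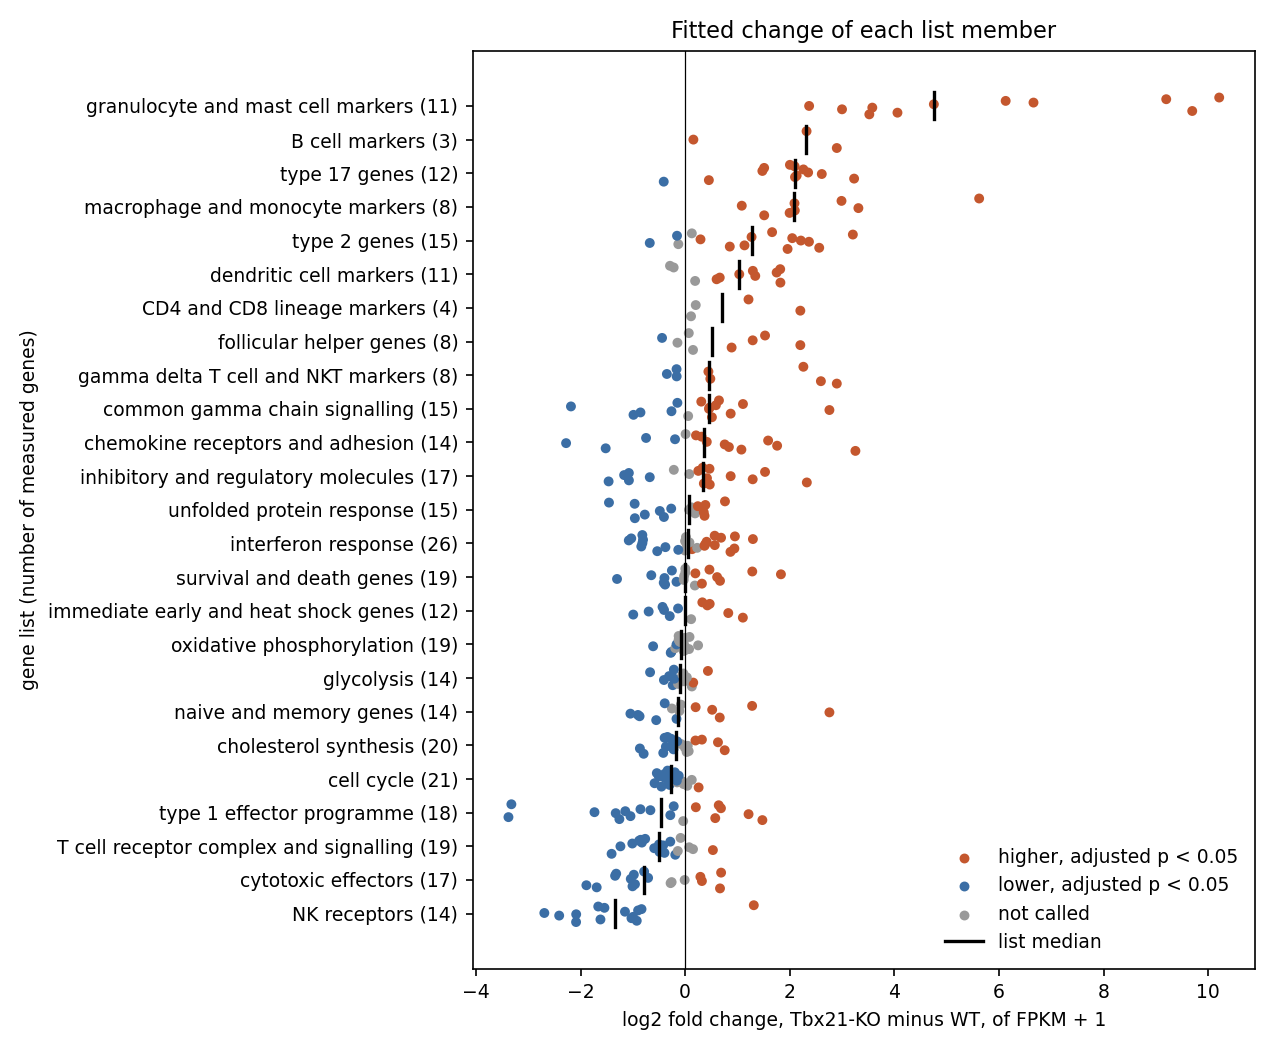
Fitted log2 fold change, Tbx21-KO minus WT, of each measured gene (points) in the 25 lists with at least 3 measured genes, ordered by median (black bars), with the number of measured genes in parentheses. Orange points were called higher, blue points lower and grey points not called. The medians run from -1.35 for NK receptors to 4.76 for granulocyte and mast cell markers, and the T cell list scaling moved the median of all genes to the right by 0.40.

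Cell cycle genes were slightly lower: 15 of 21 measured genes fell, 1 rose and 5 were not called, also adjusted over the list alone, with a median of -0.27 (camera adjusted p = 0.000155, adjusted p = 0.37 with an estimated correlation), but with the T cell list scaling 13 rose, none fell and the camera call was lost. Pcna, Mcm5, Ccne1 and Mcm2 fell by 0.54, 0.50, 0.58 and 0.38. The gene that rose was Aurka, named after its value was seen, by 0.26, a call lost in 1 other fit. Over the 25 lists, camera called 6 higher and 5 lower with the preset correlation, and none with an estimated correlation, where 3 lists had an unadjusted p under 0.05 and adjusted p ran from 0.32 to 0.89. With 2 libraries per group that estimate rests on 2 residual degrees of freedom.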

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

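Tests on the T cell list scaling, on voom and on genes with a mean WT FPKM of at least 1 were chosen after the results were seen. Tbx21 was lower, with an adjusted p under 0.05, under every alternative, with log2 fold changes from -1.25 (pseudocount of 5) to -2.40 (voom on recovered reads). Leaving out 1 library gave -2.09 to -1.92, where the lone library of a group is assumed to vary like the other group. Leaving out 1 library gave 2391 to 3036 higher genes and 1726 to 2225 lower genes, with the low ends without Tbx21-KO cDNT 1, and 6 lists higher and 5 to 6 lower.

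Against 3315 higher and 2531 lower genes, a mean FPKM of at least 5 gave 2018 higher of 7032 tested (fewer genes tested), and a log2 fold change of at least 1 left 869 higher and 205 lower by construction. Quantile normalization gave 3801 lower genes, with the median gene moved by -0.14, and the cause was not tested. Rescaling to the T cell receptor list gave 7906 higher and 508 lower, since it raises the Tbx21-KO values of all genes against WT. With the T cell list scaling 585 genes called lower became called higher. An estimated inter-gene correlation called 0 lists higher and 0 lower with camera (3 at an unadjusted p under 0.05). Against 5 lists lower, no filter gave 8, and a mean FPKM of at least 5 and quantile normalization gave 3 each; the cause was not tested for these list counts.

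Among 164 named genes other than Tbx21, none changed sign with an adjusted p under 0.05 before or after, except under the T cell list scaling, where 19 did, by construction of that scaling: Mcm2 0.07, Ldha 0.06, Pfkp 0.15, Atp5a1 0.19, Atp5b 0.20, Ndufa9 0.29, Sqle 0.056, Stat4 0.21, Havcr2 0.17, Bhlhe40 0.43, Gzme 0.20, Gzmg 0.45, Gata3 0.28, Il4ra 0.30, Tcrg-C2 0.30, Tcrg-C4 0.11, Trgv2 0.30, Cd3g 0.32 and Zap70 0.37 (log2). Of these 164 genes, 26 lost a call in at least 1 fit (64 calls in all). In fits fixed in advance 15 did: Trgv2 in 9 fits, Stat4 in 7, Ighm in 6, Ndufa9 and Tcrg-C2 in 5, Il4ra in 4, Gzmm in 3, Cd5 and Lamp1 in 2, and Il10, Aurka, Ccl5, Gzmf, Havcr2 and Runx3 in 1. Fits chosen later took 1 more call each from Trgv2, Gzmm, Il10 and Havcr2. Ahr, Ccne1, Cd3e, Cycs, Ldha, Mcm2, Mcm5, Pcna, Pfkp, Sqle and Tcrg-C4 lost it only with the T cell list scaling.

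Replicate numbers 1 and 2 occur in both groups, but no label says that they pair the libraries, and the deviations of same-numbered libraries correlated at -0.025 across genes, which are not independent replicates. With a replicate block 3245 genes were higher and 2482 lower, 6 lists were higher and 5 lower, and Tbx21 was at -2.01. With the replicate block Stat4 and Trgv2 lost their calls (adjusted p = 0.0654 and 0.0679).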

Other observations

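The unfolded protein response list moved both ways (7 lower and 5 higher of 15, also adjusted over the list alone, median 0.07, mean -0.19, camera direction lower, adjusted p = 0.433, adjusted p = 0.57 with an estimated correlation), with Xbp1 higher by 0.76, while Trib3 fell by 1.46, Asns fell by 0.96 and Sesn2 fell by 0.97. In the common gamma chain list, 9 of 15 genes rose and 5 fell (median 0.46, camera adjusted p = 0.355): Il7r rose 7.80-fold to 43.8 FPKM and Il2ra by 0.87, while Pim2, a survival kinase, fell to 21.3% of WT and Il21r by 0.99. Among chemokine receptor and adhesion genes 9 of 14 rose and 4 fell (median 0.36, camera adjusted p = 0.193). With the T cell list scaling the unfolded protein, common gamma chain and chemokine receptor lists had 9, 12 and 11 genes higher and 4, 3 and 3 lower. Ccr1, which myeloid cells also express, rose by 3.26 and Cxcr4 by 1.76, while Itga1 fell by 2.28. S100a9 and Lyz2, which mark myeloid cells, were at 3962 and 207.0 FPKM in the same libraries.

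The other lists were not called by camera with the deposited values. Some were in other fits: oxidative phosphorylation lower with TPM, median-of-ratios scaling, no filter and without WT cDNT 1, cholesterol synthesis lower with no filter and voom, and glycolysis lower with no filter. Follicular helper genes were called higher with no filter and at a mean FPKM of at least 5, and chemokine receptor and adhesion genes after quantile normalization. Naive and memory genes had 5 higher and 6 lower of 14 (median -0.14, mean 0.07, camera direction lower, adjusted p = 0.433), with Il7r and S1pr1 higher and Foxp1 lower. Survival and death genes had 7 higher and 7 lower of 19 (median 0.00, mean 0.10, camera direction lower, adjusted p = 0.784), with Fas higher by 1.28, while Bcl2l11 fell by 1.30. Interferon response genes had 11 higher and 9 lower of 26 (median 0.06, adjusted p = 0.784), with Oas2 higher and Isg20 and Irf8 lower. Glycolysis had 2 higher and 6 lower of 14 (median -0.09, adjusted p = 0.112), oxidative phosphorylation 0 higher and 4 lower of 19 (median -0.07, adjusted p = 0.0819) and cholesterol synthesis 4 higher and 11 lower of 20 (median -0.18, adjusted p = 0.0719). With the T cell list scaling these counts were 11 higher and 1 lower, 18 and 0, and 14 and 2, with medians of 0.37, 0.39 and 0.26. The same scaling gave 8 higher and 3 lower for naive and memory, 14 and 2 for survival and death, 18 and 6 for interferon response, 6 and 0 for follicular helper and 8 and 2 for immediate early and heat shock genes. Ldha, Atp5a1 and Cyp51 fell by 0.41, 0.28 and 0.79, and with the same scaling Ldha and Atp5a1 turned around, to 0.06 and 0.19. Follicular helper genes had 4 higher and 1 lower of 8 (median 0.52, adjusted p = 0.158), with Cd200 and Cd40lg higher. Immediate early and heat shock genes had 5 higher and 6 lower of 12 (median -0.01, mean 0.03, camera direction lower, adjusted p = 0.738), with Fos and Dusp1 higher and Egr2 and Fosb lower. Adjusted over the list alone, the counts differed for survival and death (8 higher, 7 lower), interferon response (12 and 9), immediate early and heat shock (6 and 6) and oxidative phosphorylation (0 and 3). At a mean FPKM of at least 1, too few members were measured to test the erythroid and platelet list, whose Ppbp and Itga2b rose, and the stromal list, whose Pecam1 rose and Epcam fell. With no filter the erythroid and platelet list was tested and called higher.

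The tests below were chosen after the result was seen, except the tests on the second granulocyte list and the second gamma delta 17 list, whose genes were written down before their values were looked at.

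Granulocyte transcripts in both Tbx21-KO libraries are the largest change in the data by fold. Of 33 further granulocyte genes, 25 were measured and 100% of them rose. In WT, 9 of the 25 were at 1 FPKM or more. The others passed the filter only through the Tbx21-KO libraries, which fixed the direction of their change, so only the rise of the 9 is informative. The most abundant were Pglyrp1, Ncf1 and Ncf4, at 83.4, 70.2 and 63.6 FPKM in Tbx21-KO and 6.23, 15.1 and 46.1 FPKM in WT. The lowest median log2 fold change of the first granulocyte and mast cell list under any of the 4 scalings was 4.63. These scalings moved the median of all genes by only -0.14 to 0.40, so they could not have removed the rise. It is thus far larger than the scalings differ, and a depth difference was not tested. Granulocyte-lineage or precursor cells among the sequenced Tbx21-KO cells are a candidate source, and the labels name no sort or gate that would remove them. The same genes switched on inside T cells cannot be told apart from it in bulk RNA. The T cell receptor list had a median of -0.49, with an SD of 0.49 over its members. A spread this wide decides nothing, since effects on those genes, or dilution by cells that express some of them, would both give it.

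Lower NK receptor and cytotoxic genes could come from dilution of T cell RNA by such cells. For the NK receptors the values argue against an even dilution as the whole cause, if the diluting cells lack the genes of the T cell receptor list. The NK receptor median minus that of the T cell receptor list was -0.86 on the log2 scale (permutation of genes between the lists, two-sided p = 0.00048, genes not being independent). Absence of the T cell receptor list from the diluting cells was not tested. It need not hold for members such as Ptprc and Lcp2, which myeloid cells express as well, so the list may understate a dilution. Of the 10 cytotoxic genes called lower, 9 kept the call when the libraries were rescaled to the T cell receptor list. Each of the 10 falls was larger than the shift of that scaling, so most calls were likely to stay. Over all 17 measured cytotoxic genes it gave 6 higher and 9 lower, with a median of -0.43. Of 23 NK receptor and cytotoxic genes called lower, at least 22 kept the call under each of the 4 scalings. These scalings moved the median of all genes by only -0.14 to 0.40, against medians of -1.35 and -0.78 for the NK receptor and cytotoxic lists. Most calls were therefore likely to stay, and the count shows only that most of these falls were larger than the scalings differ. The counted library totals given above were close, which argues against a difference in counted depth for these falls. What stays open is an effect of the Tbx21 change within the cells, or a different mix of T cell or NK-like cells, neither of which was tested. Dilution also stays open for the cytotoxic list as a whole.

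Higher type 17 genes may come from more interleukin-17-producing gamma delta T cells. Of 12 further genes of such cells, 9 were measured and 100% rose. In WT, 5 of the 9 were at 1 FPKM or more, and the direction of the others was fixed by the filter. The most abundant were Serpinb1a and Ckb at 76.5 and 55.2 FPKM in Tbx21-KO, and neutrophils express Serpinb1a as well. The gamma delta and NKT list was mixed (5 higher and 3 lower of 8, median 0.46, camera adjusted p = 0.209). Sox13, Zbtb16, Blk and Trdc rose by 2.60, 2.26, 2.90 and 0.45. The remaining riser was Tcrg-C1, named after its call was seen. Tcrg-C2, Tcrg-C4 and Trgv2 fell by 0.16, 0.35 and 0.16, so the gamma chain genes moved both ways. The T cell list scaling turned these falls around, and the calls of Trgv2 and Tcrg-C2 were also lost in 10 and 5 other fits. Trdv4, a delta chain variable segment, rose 5.59-fold to 134.8 FPKM and Cd163l1 11.3-fold to 83.1 FPKM. Of 18 Trbv segments 15 fell, of 24 Trav segments 15 fell, and none rose. With the T cell list scaling these were 12 lower and 0 higher, and 10 lower and 2 higher. These genes were chosen after their values were seen. Trdv4 is 1 segment picked from its family, whose other members are not given here. Some Trav segments are shared with the delta chain, as their names show, so the contrast is not clean. All 11 type 17 genes called higher kept the call under each scaling. The scalings moved the median of all genes by only -0.14 to 0.40, too little to undo most rises in a list with a median of 2.10. A type 17 programme within the same T cells stays open, as untested.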
